A study of Homo sapiens with 9 samples.

How the data were processed

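RNA was measured in HEK293T cells, an established human embryonic kidney line that carries adenoviral and SV40 T antigen sequences and takes up plasmids readily. The cells had been transfected with 3 µg of plasmid in all and were harvested 72 hours later, per the labels' protocols. The plasmids encoded Cascade, the multi-subunit RNA-guided DNA-binding complex of a type I CRISPR system, with or without a fusion to the activator p300, a histone acetyltransferase. The CRISPR RNA (crRNA) was directed either to IL1RN or to GFP, a gene of jellyfish origin. The 9 libraries form 3 groups of 3: Cascade with the IL1RN crRNA, Cascade-p300 with the GFP crRNA, and Cascade-p300 with the IL1RN crRNA. Polyadenylated RNA was made into strand-specific libraries, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The sequences and target positions of the crRNAs are not given in the sources used here, so matches elsewhere in the genome were not searched.

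Reads were aligned with STAR 2.4.1a to hg38 and counted with featureCounts from Subread 1.4.6-p6, per the submitters' processing notes, whereas the file headers name featureCounts 1.4.6-p4. Per the file headers, fragments were counted when both ends aligned, with the reverse strand setting, and a fragment with several alignments was counted as a fraction at each. The values deposited are therefore expected counts, estimated fragment counts per gene that need not be whole: between 52.4% and 55.2% of the values above 0 in a library were whole, to within 0.005. Each of the 41925 genes was given as its full span, introns included, and 1841 genes had more than 1 locus. No gene on the mitochondrial chromosome was among them, and every entry named a gene. Library totals lay between 32435646 and 37605739 fragments. Near-identical copies such as HSPA1A and HSPA1B, RFPL4A and RFPL4AL1, or ribosomal protein genes and their pseudogenes share fragments under this counting, so their individual values are uncertain. Genes that overlap on one strand are uncertain as well, and reads from a p300 plasmid cannot be told from reads of the EP300 gene in counts per gene.

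The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, two-sided, TMM scaling, genes kept by filterByExpr). All 9 libraries entered 1 model with 1 coefficient per group, and 18050 genes were tested. The design had assumed whole counts, and the rounding was the only change that the unit required. A gene was called past the threshold at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are TMM-normalised CPM (fragment counts scaled to a common library size), given as mean ± SD over 3 libraries. Where a group held 0 fragments of a gene, the fold was computed against a floor of 3 fragments over the group. Where it held 1 to 3, the ratio is given with an exact 95% counting interval. Floors and intervals cover counting error only, and amplified reads without molecular identifiers are not independent molecules.

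Of 25 gene lists fixed before the data were examined, 22 had at least 5 tested members and were tested with camera (limma 3.58.1, preset correlation of 0.01), adjusted over the 66 tests of 22 lists in 3 comparisons. Each list test was repeated with an estimated correlation and with fry, which asks whether a list's own genes move on balance one way. Named genes were chosen by a rule fixed before the data were examined. It took IL1RN and EP300, and the 10 largest increases and decreases among called genes with a mean of at least 1 CPM and groups that did not overlap, which chance gives for 10% of genes with 3 libraries against 3. It also took the 3 members with the smallest p of each list that passed its test or held a called gene, and every tested gene within 1 Mb of IL1RN. Gene types came from RefSeq by symbol, and 96.6% of the tested genes had one. Transcript GC content came from GENCODE and was found for 93.1%.

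The alternatives were DESeq2 1.42.0 size factors, library totals without further scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the DESeq2 test, limma-voom, a fit of only the 6 libraries compared, the replicate number as a block, and each library left out in turn. Leaving out pseudogenes, correcting for GC content or gene length, and the replicate block with only the 6 libraries compared were added after the data had been seen. The labels give no meaning to the replicate numbers. Deviations from the group means of libraries with the same number, over 11498 genes, correlated at 0.232, 0.285 and 0.157 between the Cascade-p300 groups and at 0.26, 0.313 and 0.223 between the IL1RN crRNA groups. Between Cascade-p300 with the GFP crRNA and Cascade they correlated at -0.243, 0.372 and -0.306. From these values alone the numbers were read as pairing the samples in the first 2 comparisons, where every correlation was above 0, and not in the third. A batch behind the numbers would be expected to pair the samples in the third as well, so this reading is uncertain. It was also taken from the counts that were then tested, so fits with the block may call too many genes. The corrections took a lowess curve with a span of 0.3 from each library's log2 CPM deviations. The main gene test was tried on simulated counts with 200 changed genes per comparison, drawn from genes with a mean of at least 1 CPM. Recovery of less abundant genes was therefore not measured. The list test and the GC and length corrections were tried on simulated changes between the 2 Cascade-p300 groups only. The other alternatives were not tried on simulated counts. In the simulation of the comparison of the 2 Cascade-p300 groups, where 17877 genes were tested, 80% of 50 genes changed by 1.25-fold and 96% of 50 changed by 1.5-fold were recovered. All 50 genes at 2-fold and all 50 at 4-fold were recovered, with 9 false calls among 197. For p300 with the IL1RN crRNA against Cascade, where 17902 genes were tested, 66% were recovered at 1.25-fold and all at larger folds, with 15 false calls among 198. For p300 with the GFP crRNA against Cascade, where 17869 genes were tested, 76% were recovered at 1.25-fold, 94% at 1.5-fold, 98% at 2-fold and all at 4-fold, with 10 false calls among 194. Replicates within each group differed by more than counting noise in every pair, with a chi-square per degree of freedom of 3.36 to 8.90, so none was treated as a duplicate.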

Results

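The series measured the transcriptome of HEK293T cells after transfection of a type I CRISPR Cascade complex, with or without the p300 activator, together with a crRNA to IL1RN or to GFP. Each of the 3 groups held 3 libraries. The totals were 37605739, 37466687 and 32435646 fragments for Cascade with the IL1RN crRNA, and 33192103, 34166712 and 34846661 for Cascade-p300 with the GFP crRNA. For Cascade-p300 with the IL1RN crRNA they were 33978788, 36616528 and 36458374. The design text asks how far expression changes across the transcriptome when Cascade activates a gene.

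IL1RN, which encodes the interleukin-1 receptor antagonist, lies on chromosome 2 from 113099365 to 113134016 on the plus strand (hg38). Its level was 3.88 ± 0.639 CPM (SD, n = 3) with Cascade-p300 and the IL1RN crRNA, from 151, 116 and 145 fragments. Cascade without p300 and with the same crRNA gave 0 fragments in all 3 libraries, which allows a level of up to 0.0281 CPM over the group. Cascade-p300 with the GFP crRNA gave 1.5 fragments, rounded to 2, in 1 library and 0 in the others. EP300, the gene of p300 on chromosome 22 from 41092610 to 41180077, was at 147 ± 4.60 CPM (SD, n = 3) with Cascade alone. It was at 420.4 ± 21.3 CPM (SD, n = 3) with Cascade-p300 and the GFP crRNA, and at 367 ± 25.4 CPM (SD, n = 3) with Cascade-p300 and the IL1RN crRNA. Fragments of the p300 plasmid are part of these EP300 levels if they align to the gene.

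**Figure D1:**
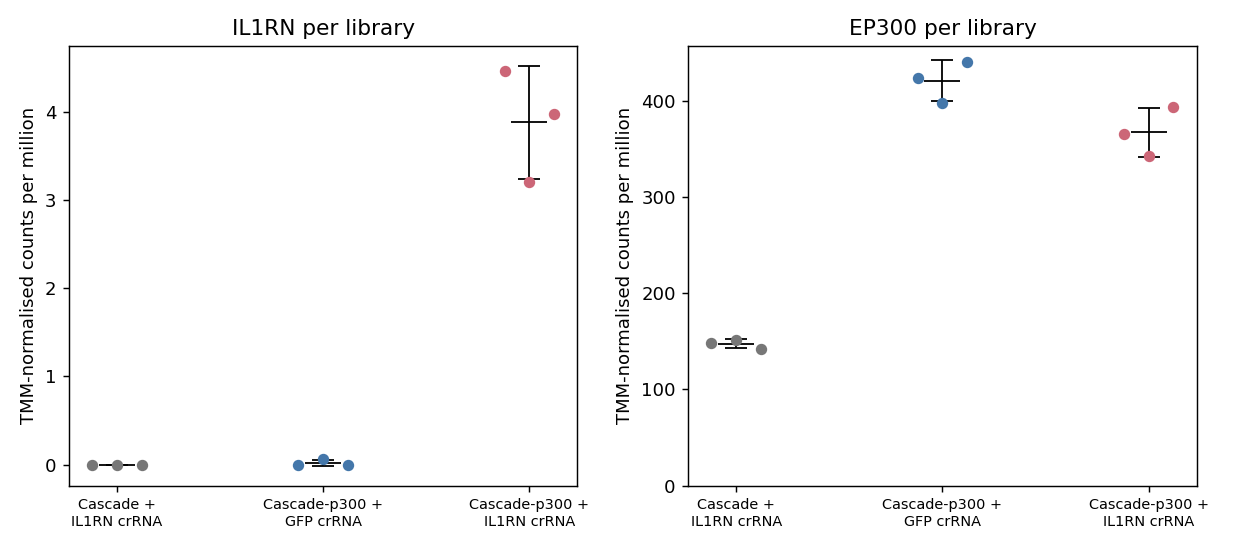
IL1RN (left) and EP300 (right) in TMM-normalised CPM on linear axes, 1 point per library, with the mean and SD of each group of 3 in black. IL1RN lies between 3.20 and 4.46 CPM in the Cascade-p300 + IL1RN crRNA libraries and at no more than 0.0581 CPM in the other 6; EP300 is higher in the 6 Cascade-p300 libraries than in the 3 Cascade libraries.

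The first comparison changed only the crRNA, from GFP to IL1RN, with Cascade-p300 in both groups. IL1RN was the largest increase of any tested gene, with a CPM ratio of 199 and a counting interval of 54.8 to 1651 (edgeR adjusted p = 7.54e-09). By size the next named increases were MIR6723 at 1.44 ± 0.0659 against 0.774 ± 0.102 CPM and LOC400927-CSNK1E at 16.1 ± 1.73 against 12.8 ± 0.837 CPM (SD, n = 3). The long non-coding RNA CRNDE rose from 83.1 ± 0.818 to 100.5 ± 3.99 CPM (SD, n = 3), a log2 fold change of 0.28 ± 0.04 (SE), and SENP7, a SUMO protease, rose by 0.27 ± 0.05. The largest decreases included pseudogenes: RPS6P10 went from 8.34 ± 0.283 to 2.27 ± 0.105 CPM and RPS11P5 from 12.9 ± 0.337 to 3.95 ± 0.311 CPM (SD, n = 3), both with an edgeR adjusted p of 7.9e-10.

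In total 54 genes were higher and 201 lower with the IL1RN crRNA among 18050 tested by edgeR, and 2989 had an unadjusted p under 0.05. Of the 201 lower genes 140 were pseudogenes, and 101 of these were pseudogenes of ribosomal proteins. No pseudogene was higher. The median log2 fold change was -0.22 over the 417 tested ribosomal protein pseudogenes. Only IL1RN rose by at least 2-fold, whereas 91 genes fell by that much. The median rise of called genes was 0.17 on the log2 scale. With library totals as the only scaling the split was 11 higher and 227 lower. The total fell to between 115 and 148 when any 1 of the 6 libraries was left out, with 4 to 20 higher, and to 29 when pseudogenes were left out of the test, 4 higher and 25 lower. With only the 6 libraries compared it was 607, with 156 pseudogenes among 387 lower genes. With the replicate number as a block as well it was 1592, with 195 pseudogenes among 787 lower genes and 25 among 805 higher. Pseudogenes were thus the minority of the lower genes in both these fits. Their share there was still larger than among all tested genes, 1891 of 18050 in the main fit. Without 1 of the 6 libraries 85 to 99 pseudogenes were lower. After correction for gene length 101 pseudogenes were lower, and 21 of the 48 higher genes were pseudogenes.

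Among the lists, immediate-early genes were lower as a group, with 0 of 37 members higher and 2 lower over all genes and 3 lower adjusted over the list alone (camera adjusted p = 0.00094). The list did not pass with an estimated correlation (adjusted p = 0.701), with fry (adjusted p = 0.173) or without IL1RN crRNA replicate 2 (adjusted p = 0.0642). DUSP1, a phosphatase of MAP kinases, fell by 0.32 ± 0.06 (SE) on the log2 scale and the transcription factor FOS by 0.47 ± 0.10. Cytosolic ribosomal protein genes were higher as a group, with 2 of 75 members called higher (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.57e-05): RPS15A by 0.18 ± 0.04 and RPL26 by 0.14 ± 0.03. That list was at an adjusted p of 0.701 with an estimated correlation and 0.109 with fry. G2/M genes (0 of 38 called, camera adjusted p = 0.00111) and p53 targets (1 of 31 higher, CCNG1 by 0.21 ± 0.05, and 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0229) also stood higher. With an estimated correlation these were at an adjusted p of 0.701 and 0.729, with fry at 0.109 and 0.372, and the G2/M list was at 0.0528 after GC correction. Neuronal and adrenal lineage genes stood lower, with 2 of 23 members called lower, TUBB3 and CHGA, and 5 adjusted over the list alone (camera adjusted p = 0.0337). That list passed fry (adjusted p = 0.00368), but not with an estimated correlation (adjusted p = 0.392) or after GC correction (adjusted p = 0.12). The heat shock genes HSPA1A and HSPA1B fell by 0.32 ± 0.07 and 0.30 ± 0.07, while their list did not pass (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.282). Of the 63 genes named by the rule besides IL1RN and EP300, 29 were called, and 16 of these lost their call without at least 1 of the 6 libraries, among them HSPA1A, HSPA1B, FOS, CCNG1, RPS15A, RPL26, TUBB3 and CHGA. With pseudogenes left out 15 of the 19 called that were still tested lost it, among them MIR6723, LOC400927-CSNK1E and these genes except FOS. Without IL1RN crRNA replicate 2 the p53 list was at an adjusted p of 0.678. It was at an adjusted p of 0.14 without GFP crRNA replicate 3, and the neuronal list at 0.0577 and 0.0757 without GFP crRNA replicate 1 or IL1RN crRNA replicate 3. EP300 fell by 0.20 ± 0.05 (SE) on the log2 scale (edgeR adjusted p = 0.0368). That call ended when any 1 of 4 libraries was left out, GFP crRNA replicate 1 or 3 or IL1RN crRNA replicate 1 or 2, with an adjusted p of up to 0.221.

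**Figure D2:**
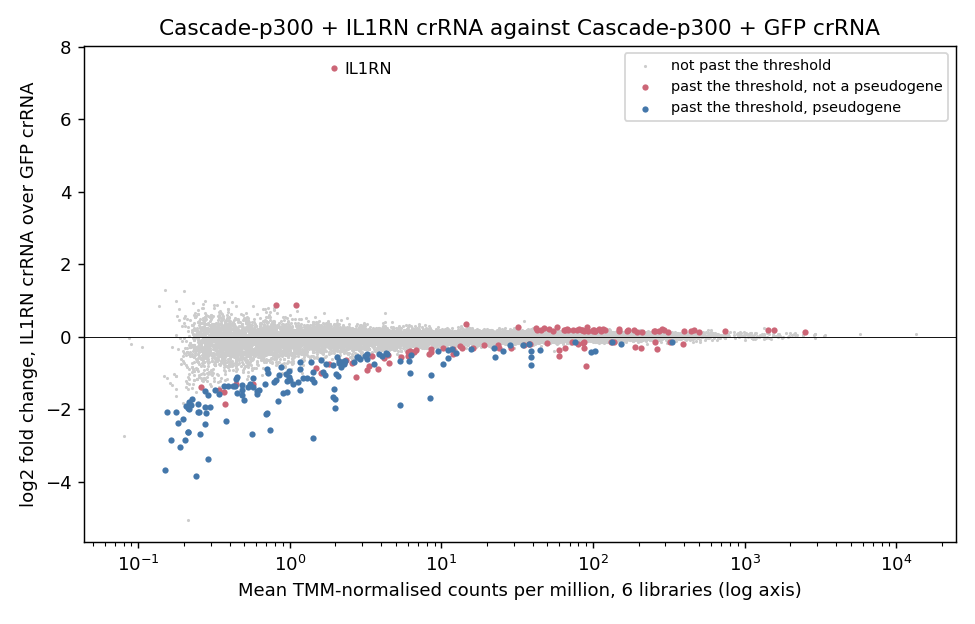
Log2 fold change of the IL1RN crRNA over the GFP crRNA with Cascade-p300 against the mean TMM-normalised CPM of the 6 libraries (log axis), 1 point per tested gene, with genes past the threshold split into pseudogenes and others. IL1RN stands apart at the top, and 140 of the 201 genes called lower are pseudogenes.

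None of the 23 other tested genes within 1 Mb of IL1RN passed the threshold over all genes in this comparison, where edgeR gave 2989 genes an unadjusted p under 0.05, and 1 passed adjusted over these genes alone. The DESeq2 Wald test and limma-voom also called 0 of them over all genes. This was FBLN7, an extracellular matrix gene, at 4.46 ± 0.719 against 5.91 ± 0.496 CPM (SD, n = 3; edgeR adjusted p = 0.0446). The 23 log2 fold changes ran from -0.71 for RPS20P11 to 0.15 for LOC105373562. PSD4, next to the interleukin-1 cluster, was at 5.25 ± 0.132 against 5.54 ± 0.535 CPM, and SLC20A1 at 136 ± 3.46 against 139 ± 5.96 CPM (SD, n = 3). In the fit of only the 6 libraries with the replicate number as a block, FBLN7 (edgeR adjusted p = 0.0143), ZC3H8 (adjusted p = 0.0204) and RPS20P11 (adjusted p = 0.0463) passed over all genes. The list of the interleukin-1 cluster and its flanks had 8 tested members of 18, none called.

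The second comparison kept the IL1RN crRNA and added p300 to Cascade. IL1RN was at least 138-fold higher with p300 (edgeR adjusted p = 5.45e-10), and EP300 rose by 1.32 ± 0.05 (SE) on the log2 scale (edgeR adjusted p = 7.5e-13). Heat shock genes rose: HSPA6, a stress-inducible HSP70, went from 1.57 ± 0.113 to 48.1 ± 7.80 CPM, HSPA1B from 57.2 ± 2.96 to 170.1 ± 17.9 CPM and the co-chaperone DNAJB1 from 48.9 ± 2.59 to 141 ± 14.6 CPM (SD, n = 3). Several genes that were almost silent without p300 were detected with it. RFPL4A rose from 0.0818 ± 0.044 to 5.35 ± 0.513 CPM, CRISPLD2 from 0.386 ± 0.102 to 9.97 ± 1.41 CPM and the long non-coding RNA LINC00624 from 0.235 ± 0.0674 to 6.56 ± 0.0778 CPM (SD, n = 3).

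In this comparison 2235 genes were higher and 2032 lower, together 23.6% of those tested by edgeR, and 295 rose and 170 fell by at least 2-fold. Of the 2032 lower genes 349 were pseudogenes, 217 of them of ribosomal proteins, and 61 pseudogenes were higher. The median log2 fold change of the 417 tested ribosomal protein pseudogenes was -0.30, so their fall was not particular to the comparison of the crRNAs. Leaving out replicate 1 of Cascade with the IL1RN crRNA gave 2493 genes. LINC01194 had 2 fragments over the 3 libraries without p300, a ratio of 112 with an interval of 30.7 to 932. LOC339166, LINC01647, RFPL4AL1 and HSPA7 completed the largest increases. Of the 10 largest named decreases 8 were pseudogenes of ribosomal proteins, the first of them RPL26P27, which fell by 3.06 ± 0.19 (SE) on the log2 scale. The others were the small nuclear RNA gene RNU6-1, which fell by 2.45 ± 0.18, and the semaphorin receptor PLXNB3, which fell by 1.59 ± 0.20. The libraries were made from polyadenylated RNA, and whether RNU6-1 counts measure the small nuclear RNA was not tested.

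The cytosolic heat shock list had 13 of 32 members higher and 1 lower (15 and 3 adjusted over the list alone), with a camera adjusted p of 7.41e-15. Of 23 neuronal and adrenal lineage genes 11 were higher and 1 lower (15 and 2 adjusted over the list alone, camera adjusted p = 3.88e-06). TUBB3, a neuronal tubulin, rose by 1.08 ± 0.08 (SE) on the log2 scale, the adhesion molecule NCAM1 by 0.30 ± 0.04 and STMN4 by 2.43 ± 0.35. These were the lists that also passed with an estimated correlation, each at an adjusted p of 0.0222. Ribosome biogenesis genes were lower, 18 of 37 with none higher (18 adjusted over the list alone, camera adjusted p = 8.28e-05), among them NOP14 and MYBBP1A. Cytosolic ribosomal protein genes were lower in 18 of 75 with none higher (18 adjusted over the list alone, camera adjusted p = 6.6e-06). Their adjusted p was 0.701 for each with an estimated correlation. The ribosome biogenesis list did not pass fry (adjusted p = 0.054), and the ribosomal protein list lost its call and turned direction with the correction for gene length (adjusted p = 0.742).

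Of 31 p53 targets 14 were lower and 2 higher (17 and 3 adjusted over the list alone, camera adjusted p = 0.00094), the repair gene DDB2 falling by 0.46 ± 0.05 (SE) on the log2 scale and the kinase PLK2 rising by 0.63 ± 0.10. The list did not pass with an estimated correlation (adjusted p = 0.701) or with fry (adjusted p = 0.0708). Of 40 DNA replication genes 11 were lower (11 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0208), CDT1 by the log2 change of -0.37 ± 0.04, and of 43 oxidative phosphorylation genes 7 were lower (6 adjusted over the list alone, camera adjusted p = 0.0362). Neither passed with an estimated correlation (adjusted p = 0.729 for each) or with fry (adjusted p = 0.0759 and adjusted p = 0.109). Cholesterol synthesis genes were higher in 9 of 30 and lower in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0291), with an adjusted p of 0.701 with an estimated correlation and 0.0504 with pseudogenes left out. G2/M genes were higher in 10 of 38 (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0439), CENPE by 0.30 ± 0.04. The G2/M list did not pass with an estimated correlation (adjusted p = 0.729), with fry (adjusted p = 0.054), after GC correction (adjusted p = 0.45), with pseudogenes left out (adjusted p = 0.0923) or with the replicate block on all 9 libraries (adjusted p = 0.0502; 0.0471 on the 6 compared). Without Cascade replicate 2 the G2/M, DNA replication, cholesterol synthesis and oxidative phosphorylation lists were at an adjusted p of 0.0608, 0.0596, 0.0596 and 0.126. The G2/M list was at 0.105 without Cascade replicate 1. Without replicate 1 of Cascade-p300 the G2/M, cholesterol synthesis and oxidative phosphorylation lists were at 0.159, 0.136 and 0.0621, and without its replicate 3 the DNA replication and oxidative phosphorylation lists at 0.137 and 0.0902. The oxidative phosphorylation list turned direction with the correction for gene length (adjusted p = 0.926).

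**Figure D3:**
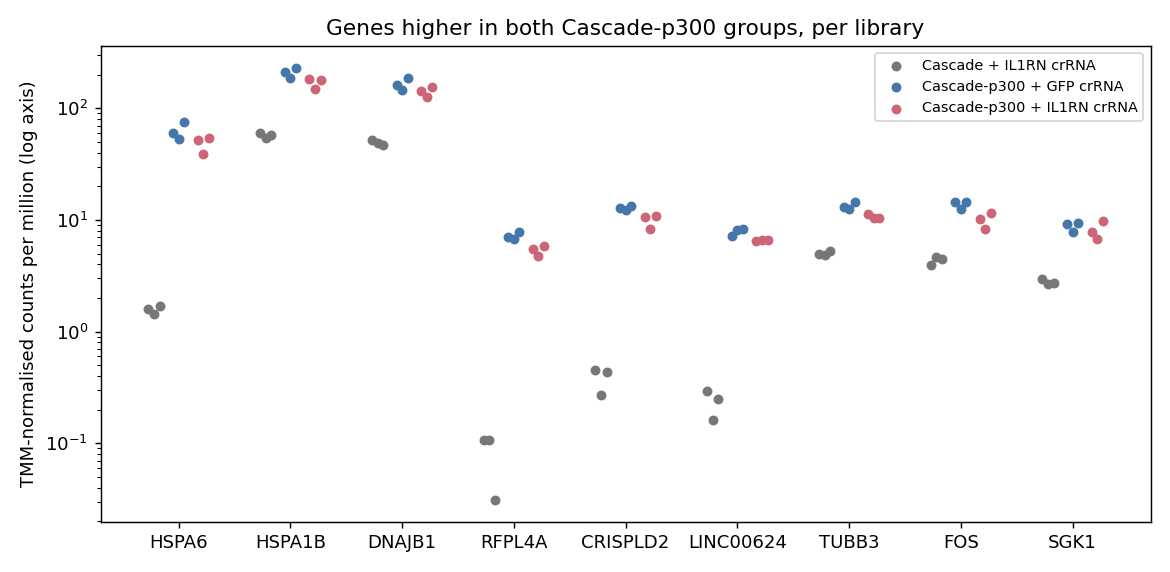
TMM-normalised CPM (log axis) of 9 genes named in the comparisons with and without p300, 1 point per library and 3 libraries per group. HSPA6 lies at 1.57 CPM on average with Cascade alone and at 62.9 and 48.1 CPM in the 2 Cascade-p300 groups.

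The third comparison set Cascade-p300 with the GFP crRNA against Cascade with the IL1RN crRNA, so that both p300 and the crRNA differed. HSPA6 was at 62.9 ± 10.9 against 1.57 ± 0.113 CPM and HSPA1A at 72.9 ± 8.50 against 19.7 ± 1.02 CPM (SD, n = 3). RFPL4A rose by 6.35 ± 0.22 (SE) on the log2 scale, CRISPLD2 by 5.04 ± 0.16 and LINC00624 by 5.06 ± 0.16. FOS rose from 4.35 ± 0.376 to 13.8 ± 1.21 CPM and SGK1, a stress-responsive kinase, from 2.77 ± 0.15 to 8.85 ± 0.855 CPM (SD, n = 3). IL1RN was at or under 3 fragments in both groups and has no fold here (edgeR adjusted p = 0.316), and EP300 rose by 1.51 ± 0.05.

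By edgeR 2124 genes were higher and 1757 lower, 21.5% of those tested, and 373 rose and 29 fell by at least 2-fold. Of the 1757 lower genes 94 were pseudogenes, 46 of them of ribosomal proteins, and 62 pseudogenes were higher. The median log2 fold change of the 417 ribosomal protein pseudogenes was -0.10 here. With library totals as the only scaling the split was 2538 higher and 1246 lower. Leaving out 1 library gave 2607 to 4206 genes. The lowest count came without GFP crRNA replicate 2, with 1619 higher and 988 lower. LINC01467 and LOC105371703 had 3 fragments each without p300, ratios of 91.5 (interval 31 to 446) and 77 (interval 26 to 376). The largest named decreases were RNU6-1, which fell by 2.11 ± 0.17 (SE) on the log2 scale, LINC00324, CCDC65 and PLXNB3.

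Of 32 heat shock genes 11 were higher and 1 lower (14 and 2 adjusted over the list alone, camera adjusted p = 2.3e-16). Of 23 neuronal and adrenal genes 15 were higher and 2 lower (16 and 2 adjusted over the list alone, camera adjusted p = 3.84e-09), with TUBB3 up by 1.41 ± 0.08 (SE) on the log2 scale and NEFH, a neurofilament, by 2.57 ± 0.26. Both lists passed with an estimated correlation at an adjusted p of 0.0222. Immediate-early genes were higher in 10 of 37 and lower in 3 (10 and 4 adjusted over the list alone, camera adjusted p = 0.00173). That list did not pass with an estimated correlation (adjusted p = 0.701) or with fry (adjusted p = 0.0521). With p300 and the IL1RN crRNA over Cascade 7 of 37 were higher and 4 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.294). Cholesterol synthesis genes were higher in 9 of 30 (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00415), with HMGCS1 at 106 ± 3.29 against 86.2 ± 3.35 CPM (SD, n = 3), and the list was at an adjusted p of 0.67 with an estimated correlation. Ribosomal protein genes were lower in 45 of 75 (54 adjusted over the list alone, camera adjusted p = 1.38e-12), RPL3 by the log2 change of -0.20 ± 0.03, and the list was at an adjusted p of 0.464 with an estimated correlation. Ribosome biogenesis genes were lower in 18 of 37 (19 adjusted over the list alone, camera adjusted p = 4.52e-05), with an adjusted p of 0.701 with an estimated correlation and 0.0521 with fry. Of 31 p53 targets 17 were lower and 3 higher (22 and 3 adjusted over the list alone, camera adjusted p = 2.8e-06), and of 40 DNA replication genes 11 were lower and 2 higher (12 and 2 adjusted over the list alone, camera adjusted p = 0.00639). With an estimated correlation the adjusted p was 0.67 for p53 targets and 0.701 for DNA replication genes, and the latter did not pass fry (adjusted p = 0.0578). G2/M genes did not pass here, with 5 of 38 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.872).

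Lists of inflammatory genes passed camera in none of the 3 comparisons, whereas NF-kappaB and interleukin-1 signalling genes passed fry as lower with p300 and the IL1RN crRNA over Cascade (fry adjusted p = 0.0268, camera adjusted p = 0.465). Of 27 tested interferon-stimulated genes 0, 2 and 3 were higher between the Cascade-p300 groups, with p300 and the IL1RN crRNA over Cascade, and with p300 and the GFP crRNA over Cascade, in that order (0, 2 and 3 adjusted over the list alone), and none lower by edgeR. The helicase regulator DHX58 rose by 1.15 ± 0.23 and 1.72 ± 0.21 (SE) on the log2 scale in the comparisons with Cascade. Of 30 NF-kappaB and interleukin-1 signalling genes 0, 4 and 3 were lower and 0, 1 and 2 higher in the same order (1, 4 and 3 lower and 0, 1 and 2 higher adjusted over the list alone). LIF, a cytokine, fell by 0.82 ± 0.13 and 0.59 ± 0.13 in the comparisons with Cascade. Of 36 lysine acetyltransferases, deacetylases and bromodomain readers 0, 2 and 6 were higher and 0, 5 and 4 lower (1, 2 and 6 higher and 0, 5 and 4 lower adjusted over the list alone). BRD2, a bromodomain reader, was at 474 ± 11 and 481 ± 9.05 CPM in the Cascade-p300 groups with the IL1RN and GFP crRNA, against 550 ± 17.5 CPM with Cascade (SD, n = 3).

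With p300 and the IL1RN crRNA 4 of the 23 neighbours of IL1RN passed against Cascade with that crRNA, over all genes and adjusted over these genes alone. ZC3H6 rose by 0.20 ± 0.05 (SE) on the log2 scale, and CHCHD5, LOC105373562 and RPS20P11 were lower. CHCHD5 and LOC105373562 were also called lower with Cascade-p300 and the GFP crRNA, and LOC105373562 alone passed there adjusted over these genes.

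Genes called the same way in both comparisons with Cascade numbered 1508 higher and 999 lower, where independent lists of those sizes would share 263 and 198. Genes that differed in Cascade-p300 with the IL1RN crRNA from both other groups numbered 11 higher, IL1RN among them, and 162 lower, of which 138 were pseudogenes. Independent lists would share 6.7 and 22.6. In 20 simulations of 3 unchanged groups with the same shared libraries, the highest overlap was 1 gene for the former and 0 for the latter. No simulated comparison called more than 7 genes, so large overlaps were ruled out there in advance and these values are no measure for lists of this size. The shared group of 3 cannot be split into parts of at least 2 libraries each, so part of the excess may come from the shared libraries. The 2507 genes of the former overlap became 1614 without Cascade replicate 1. The 173 of the latter became 97 or 99 without IL1RN crRNA replicate 3 or 1 of Cascade-p300, 110 or 113 without GFP crRNA replicate 3 or 2, and 387 without Cascade replicate 3.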

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

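Leaving out pseudogenes, the corrections for GC content and gene length and the replicate block on 6 libraries were chosen after the data had been seen. IL1RN kept its direction and its call against both other groups in every alternative run. Without 1 library its fitted log2 changes were 6.88 to 10.09 against the GFP crRNA and 9.98 to 10.21 against Cascade. Cascade held 0 IL1RN fragments, and so did the GFP crRNA group without its replicate 2, which gave the 10.09. Fitted changes against 0 fragments have no measured denominator, so their range does not measure stability. Besides IL1RN and EP300, 29, 83 and 80 named genes were called in the 3 comparisons and none of these turned direction, whereas 10, 10 and 7 named genes without a call changed sign in at least 1 alternative. Between the Cascade-p300 groups the count of 255 genes became 788 with no filter on low counts, 142 with at least 1 CPM in 3 libraries, 607 with only the 6 libraries, 1592 with these and the replicate block, 29 with pseudogenes left out and 115 to 148 without 1 library. Against Cascade with the same crRNA the count was 2493 to 5429 without 1 library, lowest without Cascade replicate 1. EP300 between the Cascade-p300 groups was at -0.204 with pseudogenes left out (edgeR adjusted p = 0.0589) and -0.175 after GC correction (edgeR adjusted p = 0.0521), and at -0.249 to -0.15 without 1 library (adjusted p 0.0146 to 0.221). The 173 genes that differed from both other groups became 367 with no filter, 104 with at least 1 CPM, 19 with pseudogenes left out and 97 to 387 without 1 library. The 2507 shared by both Cascade-p300 groups became 1614 to 3077 without 1 library. The cause of these changes was not tested.

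Within 1 Mb of IL1RN the 0 genes between the Cascade-p300 groups became 2 with no filter on low counts, 1 with only the 6 libraries, 3 with these and the replicate block and 0 to 1 without 1 library. The 4 genes against Cascade with the same crRNA became 2 with the DESeq2 Wald test, 7 GC-corrected, 2 length-corrected and 2 to 5 without 1 library. The 2 genes with the GFP crRNA became 1 with at least 1 CPM in 3 libraries, 1 with the DESeq2 Wald test, 1 with the replicate block on 6 libraries and 1 to 3 without 1 library. Of the list tests, 5 passed between the Cascade-p300 groups, 0 with an estimated correlation, 1 with fry, 3 GC-corrected and 4 to 8 without 1 library. Against Cascade with the same crRNA 9 passed, 2 with an estimated correlation, 5 with fry, of which 4 are among the 9, and 5 to 10 without 1 library. With the GFP crRNA 8 passed, 2 with an estimated correlation, 5 with fry and 8 to 9 without 1 library. In the comparison of p300 with the IL1RN crRNA, the cytosolic ribosomal protein list (adjusted p = 0.742) and the oxidative phosphorylation list (adjusted p = 0.926) turned direction when length-corrected; the cause was not tested.

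With the replicate block the counts were 310, 4728 and 4276 on all 9 libraries and 1592, 4933 and 2795 on the 6 compared. Over all 3 groups 5 of 9 libraries correlated best with their own number. On all 9 libraries the block ended the call of the G2/M list with p300 and the IL1RN crRNA (adjusted p = 0.0502) and of 2 of the 29 genes named and called between the Cascade-p300 groups. On the 6 libraries it ended no call of a named gene or list in the first 2 comparisons, and 14 and 2 named genes without a call gained one. In the third, where the numbers were read as not pairing the samples, it ended 4 of 80.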

Other observations

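The tests on parent genes, on opposite-strand genes, on gene length, on GC content by direction and on genes that rose with p300, and the versions matched for abundance or with the replicate block, were chosen after the results were seen.

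Among lists not yet described, TGF-beta, BMP and YAP targets went both ways. With p300 and the IL1RN crRNA 4 of 29 were higher and 3 lower than with Cascade (7 and 8 adjusted over the list alone, camera adjusted p = 0.897), and with the GFP crRNA 8 and 7 (9 and 7 adjusted over the list alone, camera adjusted p = 0.789). ANKRD1, a muscle ankyrin repeat protein and YAP target, rose from 5.11 ± 0.428 CPM to 10.2 ± 0.578 and 9.22 ± 0.463 CPM (SD, n = 3). Of 40 unfolded protein and integrated stress response genes 8 were higher and 4 lower with the IL1RN crRNA (10 and 8 adjusted over the list alone, camera adjusted p = 0.872) and 9 and 4 with the GFP crRNA (9 and 4 adjusted over the list alone, camera adjusted p = 0.758). DDIT3, a stress transcription factor, rose from 76.6 ± 1.92 CPM to 87.6 ± 0.614 and 92.3 ± 1.38 CPM (SD, n = 3). Of 36 hypoxia and glycolysis genes 5 were higher and 3 lower with the IL1RN crRNA (5 and 3 adjusted over the list alone) and 4 and 1 with the GFP crRNA (4 and 1 adjusted over the list alone), and the glycolytic aldolase ALDOC rose by 0.85 ± 0.09 and 1.17 ± 0.09 (SE) on the log2 scale. The median of this list was below 0 in the former comparison while its mean and test were above.

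Of 18 replication-dependent histone genes 2 were higher and 3 lower with the IL1RN crRNA and 2 and 2 with the GFP crRNA, the same counts adjusted over the list alone; in both the median and mean were negative while camera gave the direction as up. HIST1H2BD rose by 1.29 ± 0.12 and 1.15 ± 0.12 (SE) on the log2 scale. Of 10 fibroblast markers 3 were lower with the IL1RN crRNA (3 adjusted over the list alone, camera adjusted p = 0.183), among them COL1A1, a collagen chain, at 10.7 ± 1.29 against 15.7 ± 1.53 CPM (SD, n = 3), and with the GFP crRNA 1 was higher and 2 lower (the same adjusted over the list alone, camera adjusted p = 0.87). Of 7 keratinocyte markers 1 was higher and 2 lower with the IL1RN crRNA (camera adjusted p = 0.813) and 1 and 3 with the GFP crRNA (camera adjusted p = 0.872), the same counts adjusted over the list alone. TP63, an epithelial transcription factor, had 3 fragments over the Cascade libraries, ratios of 25.1 (interval 8.2 to 124.2) and 33.8 (interval 11.2 to 166.9). Of 7 lymphoid and myeloid markers 2 were lower with the IL1RN crRNA (3 adjusted over the list alone, camera adjusted p = 0.563) and 0 were called with the GFP crRNA by edgeR (0 adjusted over the list alone, camera adjusted p = 0.872). Of 8 genes often targeted with programmable activators 3 were lower with the IL1RN crRNA (3 adjusted over the list alone, camera adjusted p = 0.282), and 1 was higher and 2 lower with the GFP crRNA (1 and 3 adjusted over the list alone, camera adjusted p = 0.646). Hepatocyte and erythroid markers had 2 tested members each.

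Pseudogenes made up 140 of the 201 genes lower with the IL1RN crRNA than with the GFP crRNA. A candidate explanation is that fewer fragments of abundant parent genes were counted at pseudogenes in those libraries. Pseudogenes held 3.03 ± 0.044% of fragments with the IL1RN crRNA, 3.06 ± 0.031% with the GFP crRNA and 3.18 ± 0.036% with Cascade (SD, n = 3). The tested ribosomal protein pseudogenes summed to 10330 ± 188, 10660 ± 283 and 11640 ± 171 CPM in that order (SD, n = 3). Libraries of the 2 Cascade-p300 groups overlapped in both totals, so a lower total at pseudogenes was not clear between them. The 583 pseudogenes with a parent above 9 on the log2 CPM scale had a median log2 change of -0.21, against -0.06 for 748 with a less abundant parent, a difference of -0.144 (permutation p = 1e-05, the smallest possible), and -0.27 when matched for abundance (permutation p = 1e-04, the smallest possible). The 113 parents themselves had a median of 0.04, with 0 called lower and 2 higher by edgeR. Permutations in this test and the next shuffled genes, not libraries, so their p does not measure the spread between samples. Pseudogenes of the same parent share fragments and are not independent. Of the 140 pseudogenes 101 were of ribosomal proteins, and the split by parent was not repeated without them. Genes opposite a gene at least 20 times as abundant were also lower, by -0.094 against genes with none opposite, but by only -0.05 when matched for abundance (permutation p = 0.0012), so much of that difference may come from low abundance, and a library batch that follows the groups is open because the labels give none. TSIX, opposite XIST, was at 0.465 ± 0.018 fragments per 100 of XIST with Cascade-p300 and the IL1RN crRNA. It was at 0.873 ± 0.037 with the GFP crRNA and 0.746 ± 0.17 with Cascade (SD, n = 3). Whether this difference arose in the cells or in library preparation was not tested.

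Of the genes called between the Cascade-p300 groups 115 were not pseudogenes, 54 higher and 61 lower, most by small changes; with pseudogenes left out of the test 4 were higher and 25 lower. After correction for GC content, which 109 of the 115 had, 57 stayed called, 15 higher and 42 lower, and after correction for gene length 77, 18 higher and 59 lower. The median log2 change of the 61 lower genes was -0.39 before, -0.41 after GC correction and -0.39 after length correction, which argues against either trend as the whole cause of those 61 falls. The 19 falls that lost their call with GC correction went from a median of -0.242 to -0.179 (median SE 0.0578 and 0.0521). A part of the falls may therefore come from a GC trend. The 39 rises that lost their call with GC correction had an adjusted p of 0.0272 or more before, and their median went from 0.169 to 0.107 (median SE 0.0405 and 0.0331). The 36 lost with length correction had 0.0329 or more, with a median of 0.17 and 0.153 (median SE 0.0408 and 0.0392), so a part of the rises may come from either trend. In the fit of the 6 libraries with the replicate block, GC correction kept 116 of 780 higher calls outside pseudogenes, their median going from 0.128 to 0.07, and 194 of 592 lower calls, from -0.177 to -0.13, so a GC trend is open for this wider set in both directions. Length correction kept 472 and 519 there, at medians of 0.114 and -0.182. The GC correction also removes any biological difference that follows GC content, and a response to the IL1RN crRNA or to IL1RN itself was not tested.

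The 295 genes that rose by at least 1 on the log2 scale with p300 and the IL1RN crRNA over Cascade had a median log2 change of -0.218 between the Cascade-p300 groups, 234 of them lower and 14 called lower against 1 called higher. Simulations with equal Cascade-p300 groups gave medians of -0.01 to 0.04 in 20 draws. They drew each gene independently and left out genes that move together between libraries. Their range is therefore too narrow to judge the observed median by. Of the 295 genes 263 had a GC value, and genes without one were left uncorrected. After GC correction the median was -0.227, and -0.23 with the replicate block on the 6 libraries as well, which argues against a GC trend as the whole cause. A hypothesis is that p300 activity may have been lower in the IL1RN crRNA libraries, where EP300 was also lower. The EP300 call depended on single libraries (edgeR adjusted p of 0.0146 to 0.221 without 1 library). A difference in transfection or in library batch was not tested.

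With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 607, 3699 and 3469 genes with only the 6 libraries fitted, and the highest of the others 0 in each comparison by edgeR. Of the 10 splits 1, the real one, reached the real count each time. Every other split mixes both groups in each part, so that their differences add to the spread. Few calls were therefore likely there in advance, and the contrast decides nothing.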
